A study of Homo sapiens with 171 samples.

How the data were processed

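Expression was measured on Affymetrix arrays in 46 established ovarian cancer cell lines. Per the labels' protocols, cells were seeded overnight and then left untreated or given cisplatin for 48 h at the concentration that inhibits growth of that line to the GI50 level. The dose therefore differed between lines, and the dose of each line was not analysed here. The labels gave 171 arrays in 92 groups of line and treatment and 5 batches. Of these arrays, 4 were repeats of a numbered culture and were averaged with it, which left 167 cultures, 85 untreated and 82 treated.

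The authors deposited 1 table of log2 values for 33297 probe sets, made with RMA per the submitters' processing notes, whose version was not given in the sources used here. RMA corrects the background of each array, gives all arrays of a run the same distribution of probe values and summarises the probes of a probe set. The deposited log2 values ran from 0.469 to 14.5 with 0 missing values. The upper quartile of an array lay between 7.82 and 8.08 in batches 1 to 3 and between 5.80 and 6.59 in batches 4 and 5, so these sets of batches were on different scales. For this reason every change was taken within a line and a batch. The baseline score described below is a level compared over both sets, and an alternative standardised it within batch. Arrays carry no read depth, and their number limits the precision of each value.

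Gene symbols came from the platform annotation. Of the probe sets, 19460 had 1 symbol, 1754 had several and 12083 were not listed there. Probe sets with 1 symbol were used, and for each gene the probe set with the highest mean over all arrays was kept, which gave 18417 genes; 769 genes had several probe sets. Symbols were brought up to date through the gene identifier with a RefSeq gene table of assembly GRCh38.p14, which matched 19429 probe sets. That table also gave the genomic length of 18389 genes. No coordinates were printed because the build of the array annotation was not stated. Histone genes and other near-identical copies share probe sequence, so their separate values are uncertain.

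Comparisons were computed in R 4.3.3 with limma 3.58.1. For the effect over all lines, the mean of the treated cultures minus the mean of the untreated cultures of the same line and batch gave 1 difference per gene and line, and these 46 differences were tested against 0 with lmFit and eBayes. Treated and untreated cultures were thus paired by the line they came from, as the labels give it. Related lines, such as HeyA8 and HeyC2, entered as separate lines although they may not be independent. OVCA433, with cultures in batches 2 and 4, had its within-batch differences combined by least squares. The untreated cultures of PA-1 and SKOV-3 in batch 5 had no partner in their batch and stayed out, which left 165 cultures. Within the 18 lines of batches 1 to 3 that had replicates, a group-means model shared 1 estimate of the spread per gene with 71 residual degrees of freedom. That model gave a contrast per line, an F test of the differences between lines and 3 contrasts between related lines. Benjamini-Hochberg adjustment was used throughout, with a threshold of 0.05.

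A baseline score was the mean of 23 epithelial genes minus the mean of 24 mesenchymal genes on the untreated arrays. The slope of each gene's difference on this score, per standard deviation, was tested with limma over 18370 genes outside those lists. For 27 gene lists, the mean change of the members minus the median change of all genes was taken per line and tested with a two-sided sign-flip permutation test of 100000 resamples, whose smallest p is 1e-05. The test camera, with a preset correlation of 0.01 and with an estimated correlation, was an alternative. Correlations used permutation tests with the same number of resamples. Lists, the comparisons and their tests, most alternatives and the rule for named genes were fixed before the data were examined; those added later are named as such.

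Named genes were the 15 largest changes in each direction among genes past the threshold with the same sign in at least 37 lines, up to 4 members of each list past the threshold or up to 2 of a list with none, and a fixed set (CDKN1A, MDM2, GDF15, FAS, CCNB1, PLK1, CDH1, VIM, ZEB1, EPCAM, SLC31A1, ATP7B, ERCC1, BRCA1). For comparisons of lines they were the genes with the largest spread or the largest differences past the threshold. Alternatives changed the pairing, the weights, the batches and lines used, the scaling of arrays, the filter on dim genes, the choice of probe set and the minimum change.

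The steps were tested on simulated data in 20 draws of 18417 genes, of which 200 were changed. Over all lines, 54.2% of changes of 0.20, 97.2% of changes of 0.40 and 100% of changes of 0.80 on the log2 scale were recovered, with a median of 2.5 false calls. Within a replicated line the shares were 1.79%, 21.6% and 83.8%, with a median of 2 false calls and 230 in the worst draw. For the contrast of C13 with A2008 they were 0.0746%, 4.55% and 48.1%, and for the F test 0.0746%, 0.746% and 28.9%. In these draws, as in those within a replicated line, the change was added to the treated cultures of C13 alone. Residuals were shuffled over all replicated cultures, which evens out spread that differs between lines. The shares for the F test therefore hold for genes that respond in a single line. For the slope on the score they were 55.8%, 96.7% and 100%.

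The deposited values were compared between arrays for quality. The treated array of Hey had the lowest correlation with the profile of its batch, 0.801, against 0.920 for the lowest of the others, and 5 arrays were nearest to an array of another line, namely those of Hey untreated, OAW28 in both arms, SKOV-6 treated and the untreated PA-1 of batch 5 that stayed out. The treated culture 1 of OVCAR-10 reached a correlation of only 0.607 with another array of its line. Lines with such arrays were kept, and the counts were repeated without Hey, OAW28, SKOV-6 and OVCAR-10. That alternative, and those that left out the lines of a batch, were chosen after seeing the data.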

Results

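The series asked how ovarian cancer cells change their gene expression under cisplatin, a platinum drug that forms adducts and crosslinks on DNA. Arrays covered 46 cell lines, each untreated and after 48 h of cisplatin. In 18 lines, measured in batches 1 to 3, each arm had 3 cultures, except that HeyA8 had 2 treated ones. The other 28 lines, measured in batches 4 and 5, entered with 1 culture per arm. The batches held 43, 38, 30, 24 and 36 arrays. Cultures of the same line, arm and batch differed by a median absolute log2 value of 0.144 per gene over 106 pairs, and repeat arrays of 1 culture by 0.173 over 4 pairs. The same line and arm measured in both sets of batches differed by 1.11 to 1.18 over 9 pairs. The labels number the cultures without saying that they were grown separately, so p-values within a line measure the spread between these samples, which may be technical.

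Over the 46 lines, cisplatin raised p53 targets, NF-kB targets and immediate early genes, and lowered histone genes. TNFAIP3, an inhibitor of NF-kB signalling, rose by 0.76 ± 0.14 on the log2 scale (SE, n = 46 lines, 1.69-fold, higher in 40 lines). HBEGF, a growth factor that binds the EGF receptor, rose by 0.73 ± 0.12, and SAT1, an enzyme of polyamine breakdown, by 0.68 ± 0.07. The histone gene H1-3 fell by 1.08 ± 0.12 and was higher in only 3 lines. QTMAN, which modifies transfer RNA, fell by 0.93 ± 0.10, and SCFD2 fell by 0.86 ± 0.10. All 6 passed the limma test at adjusted p of 0.000128 or less.

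Other strong rises were those of PPP1R15A at 0.64, TXNIP at 0.64, MR1 at 0.59, E2F7 at 0.54, STOM at 0.52 and MXD1 at 0.51. Other strong falls were BBS9 at -0.84, STX8 at -0.75, STAG1 at -0.72, TMEM117 at -0.70, CPQ at -0.67, ARL15 at -0.66, FHIT at -0.60, DPH6 at -0.60 and SLC25A21 at -0.59. These are long genes, from 325350 bp for STX8 to 1504176 bp for FHIT, and QTMAN and SCFD2 span 395002 and 493080 bp. Gene length is examined below. In total 1787 of 18417 genes passed the threshold, 917 higher and 870 lower, and 4067 had an unadjusted p under 0.05. Of the genes past the threshold, 302 had the same sign in at least 37 lines. Most changes were small, with a median absolute change of 0.23 among the genes past the threshold.

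**Figure D1:**
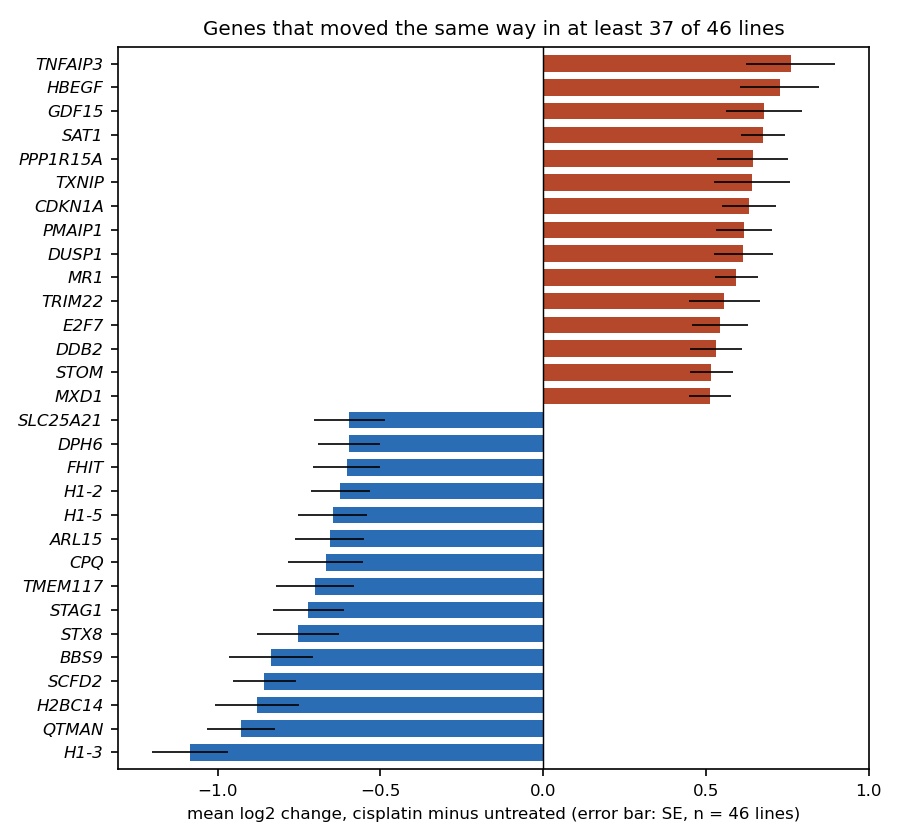
Mean log2 change with cisplatin for the 15 genes with the largest rise and the 15 with the largest fall among those with the same sign in at least 37 of 46 lines; bars start at 0 and error bars are SE over lines. TNFAIP3 rose by 0.76 and H1-3 fell by 1.08.

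The p53 target genes rose as a group. Of 35 measured, 26 rose, 0 fell and 9 did not pass, and 30 rose when adjusted over the list alone. The list mean was 0.32 ± 0.04 (SE, n = 46) above the median gene and was positive in 41 lines (sign-flip permutation adjusted p = 3.86e-05, from an unadjusted p of 1e-05, the smallest these permutations can give). GDF15, a stress-induced cytokine, rose by 0.68 ± 0.12. CDKN1A, which encodes the cell-cycle inhibitor p21, rose by 0.63 ± 0.08, and PMAIP1, a pro-apoptotic gene, by 0.62 ± 0.09. TRIM22 rose by 0.56 ± 0.11. MDM2, the ubiquitin ligase of p53, rose by 0.23 ± 0.07 (limma adjusted p = 0.02), but was at -0.12 in the lines of batch 4 alone. The list means of batches 1 to 5 were 0.46, 0.34, 0.50, 0.22 and 0.27.

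Apoptosis and repair lists had smaller means and were not independent of the p53 target list. That list also holds FAS, TNFRSF10B, TNFRSF10C, PMAIP1, BAX, BBC3, DDB2, XPC and POLH, so changes of these genes count in more than 1 list. Of 11 death receptor genes 6 rose and 7 did so adjusted over the list alone, among them FAS by 0.47 ± 0.10, TNFRSF10B by 0.37 ± 0.05, CFLAR, an inhibitor of death receptor signalling, by 0.37 ± 0.08 and the decoy receptor gene TNFRSF10D by 0.37 ± 0.08; the list mean was 0.18 ± 0.03, positive in 37 lines. Of 10 pro-apoptotic BCL2 family genes, PMAIP1 and BCL2L11 (0.21 ± 0.05) rose, also adjusted over the list alone, and the list mean was 0.11 ± 0.02, positive in 42 lines (adjusted p = 0.0824 with an estimated correlation). Of 4 anti-apoptotic genes BCL2 fell by 0.26 ± 0.05, and adjusted over the list alone 1 rose and 1 fell (list mean -0.04 ± 0.05, permutation p = 0.347 before adjustment). Of 17 nucleotide excision repair genes DDB2 (0.53 ± 0.08) and XPC (0.28 ± 0.06), which recognise damaged DNA, rose and RAD23B fell by 0.16 ± 0.04, with the same counts adjusted over the list alone; the list mean was 0.06 ± 0.03, positive in 35 lines (adjusted p = 0.607 with an estimated correlation). Of 8 translesion synthesis genes POLH (0.31 ± 0.07) and POLQ (0.29 ± 0.09) rose, also adjusted over the list alone, with a list mean of 0.13 ± 0.04, positive in 33 lines (adjusted p = 0.293 with an estimated correlation). In the lines of batch 1 alone POLQ was at -0.051.

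Fanconi and homologous recombination genes did not pass as a list (mean 0.10 ± 0.05, adjusted p = 0.0658, positive in 31 lines). Of 21 members 3 rose and 2 fell, or 10 and 2 adjusted over the list alone. EXO1 rose by 0.33 ± 0.11, XRCC2 by 0.29 ± 0.07 and FANCB by 0.21 ± 0.07, while RAD51B fell by 0.30 ± 0.07. However, EXO1 was at -0.12 in batch 1 alone and -0.011 in batch 3 alone, and XRCC2 at -0.13 in batch 1 alone. BRCA1 was at 0.21 ± 0.10 (limma adjusted p = 0.219, higher in 31 lines) and ERCC1 at 0.04 ± 0.05 (adjusted p = 0.751, higher in 28 lines).

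Inflammatory and early response genes rose together in most lines. Of 26 NF-kB target genes 15 rose and 0 fell, with 17 adjusted over the list alone, and the list mean was 0.31 ± 0.05, positive in 38 lines. The neutrophil chemokine CXCL8 rose by 0.85 ± 0.16, IL6 by 0.75 ± 0.17 and the chemokine CCL20 by 0.68 ± 0.13. The list means of batches 1 to 5 were 0.24, 0.16, 0.31, 0.51 and 0.25. Of 15 immediate early genes 8 rose and 0 fell, 12 adjusted over the list alone, with a list mean of 0.27 ± 0.04, positive in 40 lines; DUSP1 rose by 0.62 ± 0.09, JUN by 0.49 ± 0.10, EGR1 by 0.47 ± 0.15 and KLF4 by 0.42 ± 0.10. Of 25 interferon-stimulated genes 12 rose and 0 fell, 14 adjusted over the list alone, with a list mean of 0.22 ± 0.04, positive in 37 lines. HERC5 rose by 0.41 ± 0.09, OAS1 by 0.39 ± 0.06, IFIT2 by 0.37 ± 0.09 and IFIT3 by 0.37 ± 0.08.

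Replication-dependent histone genes, which are transcribed mainly in S phase, fell. Of 28 measured, 16 fell and 0 rose, 21 adjusted over the list alone, and the list mean was -0.35 ± 0.05, negative in 41 lines. H2BC14 fell by 0.88 ± 0.13, H1-5 by 0.65 ± 0.11 and H1-2 by 0.62 ± 0.09. The list means of batches 1 to 5 were -0.59, -0.33, -0.54, -0.17 and -0.31. DNA replication genes went both ways, with 4 up and 1 down of 29, or 9 up and 1 down adjusted over the list alone, and a mean of 0.08 ± 0.06 (adjusted p = 0.334, positive in 28 lines). MCM6, a subunit of the replicative helicase, fell by 0.30 ± 0.08, whereas POLA2 rose by 0.27 ± 0.09, RFC3 by 0.26 ± 0.07 and E2F2 by 0.21 ± 0.06. RFC3 and E2F2 were at -0.11 and -0.03 in batch 1 alone and POLA2 at -0.04 in batch 3 alone, and the list means of batches 1 to 5 were -0.13, 0.10, -0.13, 0.22 and 0.12. Of 29 mitotic genes 0 rose and 2 fell, 3 adjusted over the list alone, namely KIF20A at -0.39 ± 0.10 and the kinase PLK1 at -0.38 ± 0.10 over all genes; the list mean was -0.05 ± 0.06 (adjusted p = 0.51, negative in 24 lines). The cyclin CCNB1 was at -0.21 ± 0.07 (limma adjusted p = 0.0515, higher in 14 lines).

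NRF2 target genes, which include antioxidant enzymes, fell with a list mean of -0.14 ± 0.04, negative in 34 lines (adjusted p = 0.132 with an estimated correlation), and 5 of 14 fell, also adjusted over the list alone. TALDO1 fell by 0.30 ± 0.06, NQO1 by 0.28 ± 0.06, TKT by 0.25 ± 0.08 and ME1 by 0.21 ± 0.06. Oxidative phosphorylation genes fell with a mean of -0.07 ± 0.02, negative in 30 lines (adjusted p = 0.28 with an estimated correlation), and 3 of 17 fell, 4 adjusted over the list alone, led by NDUFA1 at -0.18 ± 0.06. Their means in batches 1 to 5 were -0.017, -0.036, -0.0066, -0.11 and -0.086, and the mean of the housekeeping controls was of like size at -0.06. Of 14 cholesterol synthesis genes INSIG1 alone fell, by 0.24 ± 0.06, also adjusted over the list alone (list mean -0.05 ± 0.03, adjusted p = 0.263). Of 18 ribosome biogenesis genes 4 fell, also adjusted over the list alone, among them UTP20 at -0.28 ± 0.09 and NPM1 at -0.11 ± 0.03 (list mean -0.03 ± 0.05, adjusted p = 0.635). The means of that list in batches 1 to 5 were -0.21, -0.14, -0.19, 0.18 and -0.01, with an adjusted p of 0.0469 in batch 1 alone. Of 19 ribosomal protein genes RPS23 alone fell, by 0.17 ± 0.05, also adjusted over the list alone (list mean -0.04 ± 0.02, adjusted p = 0.158).

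Platinum transport and detoxification genes fell with a list mean of -0.09 ± 0.03, negative in 34 lines (adjusted p = 0.28 with an estimated correlation), although the mean was 0.06 in the lines of batch 3. Of 14 measured 3 fell, 4 adjusted over the list alone. The metallothioneins MT1X and MT1F, which bind metal ions, fell by 0.26 ± 0.07 and 0.25 ± 0.07, and LRRC8D, a subunit of an anion channel that admits cisplatin, fell by 0.21 ± 0.05. The copper transporters SLC31A1 at 0.01 ± 0.06 and ATP7B at -0.09 ± 0.06 did not pass. In the stress response list 3 of 19 genes rose and 2 fell, or 3 and 5 adjusted over the list alone. DDIT3 rose by 0.69 ± 0.14, ATF3 by 0.38 ± 0.07 and DNAJB9 by 0.21 ± 0.05, while the endoplasmic reticulum chaperones HSPA5 and PDIA4 fell by 0.16 ± 0.05 and 0.17 ± 0.05. The mean of that list was 0.00451 and its median member -0.073, of opposite sign (adjusted p = 0.999).

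Epithelial genes had a mean of -0.00644 ± 0.0314 (adjusted p = 0.978) with a median member of 0.0183; 3 of 23 fell, also adjusted over the list alone, namely KRT19 at -0.23 ± 0.08, CLDN3 at -0.19 ± 0.06 and ESRP2 at -0.15 ± 0.05. In the replicated lines KRT19 was at 0.03 and CLDN3 at 0.02. CDH1 was at 0.05 ± 0.07 and EPCAM at 0.02 ± 0.13. Of 24 mesenchymal genes 0 passed, also adjusted over the list alone (mean 0.02 ± 0.02, adjusted p = 0.518, batch means 0.13, 0.02, 0.13, -0.01 and -0.04, adjusted p = 0.0469 in batch 1 alone), with VIM at 0.04 ± 0.07, ZEB1 at -0.05 ± 0.06, SNAI2 at 0.27 ± 0.10 and TGFBI at -0.16 ± 0.09. Of 14 TGF-beta target genes ID1 alone fell, by 0.29 ± 0.08, also adjusted over the list alone (adjusted p = 0.999 for the list). Of 15 lysosome genes 0 passed, also adjusted over the list alone, with NEU1 at 0.32 ± 0.12, and the list mean was 0.00202 with a median member of -0.0123 (adjusted p = 0.999).

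Markers of other cell types were measured as controls. Of 15 leukocyte markers LYZ rose by 0.35 ± 0.10 and CD68, which also marks lysosomes of other cells, by 0.26 ± 0.07, also adjusted over the list alone. The list mean was 0.06 ± 0.02, positive in 28 lines, with a median member of -0.000692. It passed the sign-flip permutation test (adjusted p = 0.0366) but not camera with an estimated correlation (adjusted p = 0.629). Of 11 endothelial markers 0 passed, also adjusted over the list alone, and their mean was 0.00163 (adjusted p = 0.999). Of 11 housekeeping genes 2 fell, PPIA at -0.21 ± 0.05 and PGK1 at -0.19 ± 0.04, and adjusted over the list alone 1 rose and 6 fell. The housekeeping mean was -0.06 ± 0.03, negative in 24 lines, and it was above 0 in batches 1, 2 and 3. It too passed the sign-flip permutation test (adjusted p = 0.0465) but not camera with an estimated correlation (adjusted p = 0.349). A list mean of this size can thus pass the sign-flip test in a control list.

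**Figure D2:**
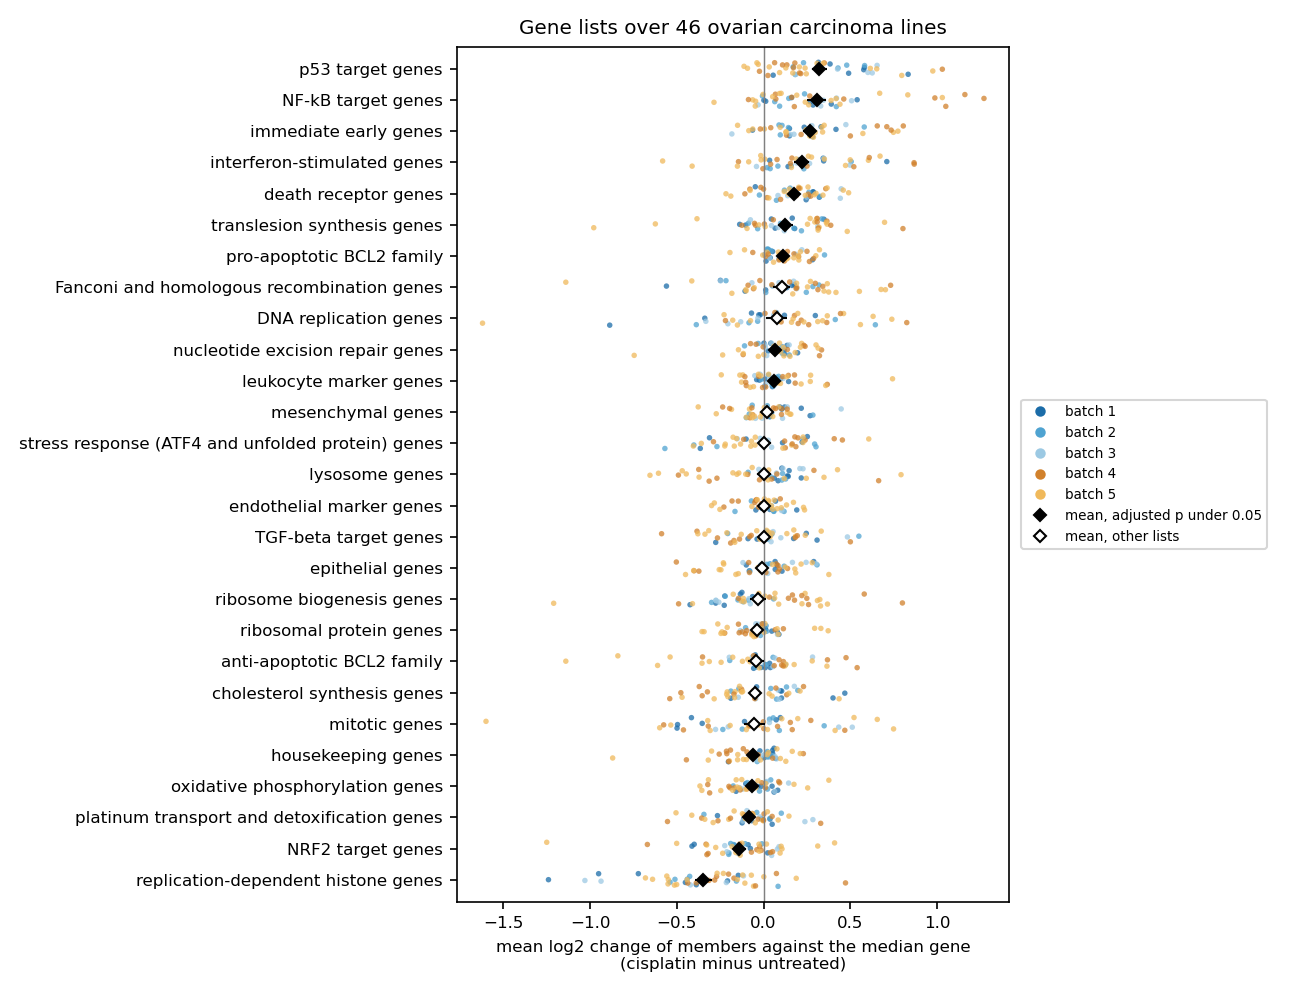
Mean log2 change of each gene list against the median gene; each point is 1 of 46 lines, coloured by batch, and diamonds with bars are means ± SE, black where the adjusted p was under 0.05. The p53 target genes lay above 0 in 41 lines and the histone genes below 0 in 41 lines.

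By the sign-flip permutation test 14 of 27 lists passed, 9 upward and 5 downward, among them the leukocyte and housekeeping controls. With camera at an estimated correlation 6 passed, namely p53 targets, histones, death receptors, NF-kB targets, interferon-stimulated and immediate early genes. For the stress response, lysosome, TGF-beta target and endothelial lists camera gave a downward direction where the mean was at or above 0. The count of genes rested in large part on batch 4: it was 627 without its 11 lines, and 2, 2, 6, 770 and 16 in batches 1 to 5 alone, while the count of lists was 9 without batch 4 and 9, 0, 0, 4 and 7 within batches. The smallest permutation p that the 5 lines of batch 3 can give is 0.0625 and that of the 6 lines of batch 2 is 0.0312, so these 0 counts do not show an absence of the changes there. With batches weighted equally 638 genes passed, and with a minimum change of 1.2-fold 6 passed.

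Within the 18 replicated lines, the response ranged from slight to extensive. FU-OV-1 changed most, with 3187 genes higher and 1931 lower. In FU-OV-1 the transcriptional regulator ID2 rose by 2.96 ± 0.24 (SE, 3 cultures per arm), the S-phase cyclin CCNE2 by 2.64 ± 0.13 and RFPL4A by 2.38 ± 0.32. STX8, a vesicle fusion protein, fell by 3.77 ± 0.15, the protease gene PAPPA2 by 3.59 ± 0.18 and the cystine transporter SLC7A11 by 3.14 ± 0.15. In TYK-nu 14 genes passed, with the immediate early genes FOS at 0.87 ± 0.11 and EGR1 at 0.81 ± 0.14 and the RNA sensor gene DHX58 at 0.61 ± 0.14, and falls of MIR302B at -1.72 ± 0.25, MIR302A at -1.63 ± 0.23 and MPP1 at -0.53 ± 0.10. These SEs come from the spread pooled over lines; the TYK-nu cultures had SDs of 0.639 untreated and 0.753 treated for MIR302B and 0.939 and 0.332 for MIR302A, with dim treated means of 3.18 and 3.13.

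The median count per line was 857 genes by limma. PA-1 had 4206, C13 3256, HeyA8 2521, OVCAR-8 2471 and OVCA420 2116 genes past the threshold, whereas DOV13B had 268 and CH1 364. Across these lines 143 genes passed in at least 9 lines and 6750 in 0. In 16 of 18 lines leaving out some single culture moved the count by more than a factor of 1.5 up or down, as 43 of 107 cultures did; OVCAR-10, with 770 genes, ranged from 16 to 1862 and TYK-nu from 6 to 123, while FU-OV-1 had 4350 to 4779 against 5118. The median was 410 with each line fitted alone, 81 with a minimum change of 1.2-fold, and 188.5 without the cultures numbered 2.

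**Figure D3:**
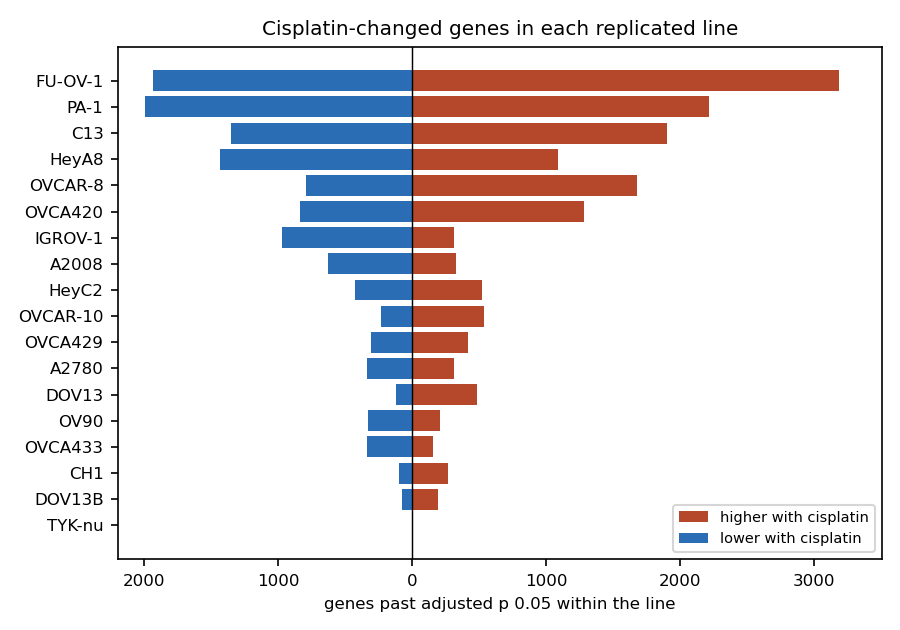
Number of genes past adjusted p of 0.05 in each replicated line, higher with cisplatin to the right of 0 and lower to the left. FU-OV-1 had 3187 higher and 1931 lower, and TYK-nu had 10 higher and 4 lower.

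The cisplatin response differed between the replicated lines for many genes. The histone gene H2BC14 ranged from -3.53 in OVCAR-8 to 0.06 in PA-1, and H3C12 from -2.42 in OVCA420 to 0.44 in OVCAR-10. The treated culture 3 of OVCA420 and the treated culture 1 of OVCAR-10 stood apart, with highest correlations to other arrays of their line of 0.857 and 0.607. CCNE2 fell by 1.46 in HeyA8 and rose by 2.64 in FU-OV-1, and FAM111B was at -1.90 in HeyA8 and 2.15 in FU-OV-1. GDF15 ran from -0.35 in FU-OV-1 to 3.71 in HeyA8, and TXNIP from -0.51 in CH1 to 3.23 in OVCA420. The mucin gene MUC13 reached 3.64 in OVCAR-8 and the metalloreductase gene STEAP4 3.31 in OVCA420, while STX8 and PAPPA2 were lowest in FU-OV-1.

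By the limma F test 9401 of 18417 genes, or 51.0%, differed between lines. All 29 mitotic and all 29 DNA replication genes did, as did 27 of 28 histone genes and 31 of 35 p53 target genes, and all 19 stress response, 15 lysosome, 14 cholesterol synthesis and 8 translesion synthesis genes, against 4 of 19 ribosomal protein genes and 2 of 11 endothelial markers. The count was 3694 without the cultures numbered 2 and 5712 without those numbered 3.

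C13, selected in cisplatin from the parent line that A2008 is named for, was compared with A2008. Of 29 mitotic genes 21 had a higher response in C13 and 0 a lower one, with a mean change of 0.39 in C13 and -0.12 in A2008. Of 28 histone genes 15 had a lower response in C13 and 0 a higher one, with means of -1.07 and -0.42. GKN2 rose by 3.40 in C13 and was at -0.27 in A2008, a difference of 3.67 ± 0.25 (SE, 3 cultures per arm in each line), and the complement protease gene C1S differed by 2.23 ± 0.27 and KRTAP3-1 by 2.11 ± 0.18. IL1R2 differed by 2.07 ± 0.44 and GPX3 by 2.04 ± 0.58, while H2BC14 differed by -2.24 ± 0.23, H2BC7 by -1.68 ± 0.30, H2AC21 by -1.53 ± 0.27 and H4C14 by -1.48 ± 0.32. DDIT3, a transcription factor of the integrated stress response, rose by 0.52 in C13 and by 2.01 in A2008.

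By the limma interaction contrast 888 genes differed between C13 and A2008, 658 with a higher and 230 with a lower change in C13. In both lines 355 genes passed with the same sign, 187 higher and 168 lower against 33.5 and 45.8 for independent lists, and 24 with opposite signs. The lines were in batches 3 and 2, so line and batch could not be separated. Each line was given cisplatin at its own GI50 level. Line and dose could thus not be separated either, here or in the other comparisons of lines. The count was 72 with these lines alone in the fit, and leaving out single cultures gave 555, 1426 and 573 without the A2008 untreated cultures 1 and 2 and treated culture 2, and 577, 1380 and 340 without the C13 untreated culture 2 and treated cultures 1 and 2.

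HeyC2 and HeyA8, sublines named after Hey and both in batch 1, shared many of their changes. Of 944 genes past the threshold in HeyC2 and 2521 in HeyA8, 575 passed in both with the same sign and 3 with opposite signs, against 30.7 up and 33 down for independent lists. Of 29 DNA replication genes 11 had a higher response in HeyC2 and 0 a lower one, with means of -0.35 and -0.87. H2BC14 was at -0.30 in HeyC2 and -2.81 in HeyA8, a difference of 2.50 ± 0.25 (SE, 3 cultures per arm, 2 treated in HeyA8), and CCNE2 at 0.36 and -1.46. H2BC12 differed by 2.13 ± 0.35, H3C12 by 2.12 ± 0.28 and the NADPH oxidase gene NOX4 by 1.67 ± 0.32. TNFSF4 was at 0.05 in HeyC2 and 2.93 in HeyA8, GDF15 at 1.08 and 3.71, DDIT3 at -0.19 and 1.85, DSC3 at -0.48 and 1.21, and IGFBP5 at 0.16 and 1.81.

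By limma 139 genes differed between HeyC2 and HeyA8, 91 with a higher and 48 with a lower change in HeyC2. The count was 74 with these lines alone in the fit, 81 with arrays centred on their median and 233 among the brighter genes; without single cultures it was 85, 83 and 38 (HeyA8 untreated 1 and 2, treated 3) and 209, 89 and 81 (HeyC2 untreated 1 and 2, treated 1).

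DOV13B and DOV13 differed in few genes past the threshold, which does not make their responses alike. Over all genes their changes correlated at 0.142, against 0.207 for C13 and A2008 and 0.454 for HeyC2 and HeyA8. Few genes passed within these lines, 268 in DOV13B and 609 in DOV13. Spread between cultures lowers such a correlation, so it does not show unlike responses either. The response of PLK1 was 0.66 in DOV13B and -0.09 in DOV13, a difference of 0.75 ± 0.14 (SE, 3 cultures per arm in each line). DDIT3 was at 0.17 and 1.39 and ATF3, another gene of the integrated stress response, at 0.18 and 0.96. SMOC1 was at 1.23 and 0.13, while CER1 differed by 1.34 ± 0.31, XXYLT1 by 0.60 ± 0.13, LURAP1L by -1.15 ± 0.22, FRRS1 by -0.87 ± 0.18 and SNORD113-3 by -1.49 ± 0.33. In both lines 98 genes passed with the same sign and 0 with opposite signs, 90 of them higher and 8 lower against 5.01 and 0.521 for independent lists.

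By limma 15 genes differed between DOV13B and DOV13, 4 with a higher and 11 with a lower change in DOV13B, which were in batches 3 and 2. The count was 8 with these lines alone in the fit and 27 among the brighter genes, and without single cultures it was 1, 6, 31 and 1 (DOV13 untreated 1, 2 and 3, treated 3) and 2, 8 and 3 (DOV13B untreated 3, treated 1 and 3).

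A2780 and A2780cisR, the latter a cisplatin-resistant derivative by name, lay in batches 1 and 4, and A2780cisR had 1 culture per arm, so their difference was not tested. The p53 target mean was 0.58 in A2780 and 0.35 in A2780cisR, and the histone mean was -0.39 and -0.44. CDKN1A was at 1.22 and 0.86, MDM2 at 0.59 and -0.39, and PLK1 at -0.80 and 1.17.

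The response was then set against the untreated epithelial minus mesenchymal score, since the series belongs to work on epithelial-mesenchymal status. The score ran from -1.92 to 3.84 without a wide gap, and it shares the untreated arrays with the changes set against it. It is a level compared over both sets of batches, whose scales differed. RNLS, a flavoenzyme gene, changed by -0.31 ± 0.06 per standard deviation of the score (SE, n = 46, limma adjusted p = 0.0177), so its change was lower in more epithelial lines. Among genes above the median in mean value 0 passed, so RNLS was too dim to enter that test or did not pass it. Over 27 lists, DNA replication genes correlated with the score (r = 0.429, permutation p = 0.00189, adjusted p = 0.0295; rho = 0.432, p = 0.00312, adjusted p = 0.0212). So did Fanconi and homologous recombination genes (r = 0.422, permutation p = 0.00292, adjusted p = 0.0295; rho = 0.442, p = 0.00225, adjusted p = 0.0212) and NF-kB target genes (r = 0.414, permutation p = 0.00408, adjusted p = 0.0295; rho = 0.425, p = 0.0036, adjusted p = 0.0212).

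Interferon-stimulated genes correlated with the score as well (r = 0.384, permutation p = 0.00816, adjusted p = 0.0441; rho = 0.436, p = 0.00262, adjusted p = 0.0212), and ribosomal protein genes did so negatively (r = -0.409, permutation p = 0.00437, adjusted p = 0.0295; rho = -0.419, p = 0.00393, adjusted p = 0.0212). The p53 target genes did not (r = -0.0997, permutation p = 0.508; rho = -0.0894, p = 0.551), nor did mitotic genes (r = 0.0504, permutation p = 0.742; rho = 0.00154, p = 0.992). Without OVCAR-8 and OVCAR-3, the lines farthest from the median score, r was 0.41, 0.396, 0.431, 0.377 and -0.367 for these 5 lists, and 0 lists passed after adjustment (adjusted p from 0.0571 to 0.0727, n = 44). The other 20 lists had r between -0.215 and 0.255.

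Within batches the relations were uneven. For DNA replication genes r was 0.501, -0.442, 0.456 and 0.685 in batches 1, 2, 4 and 5, with 7, 6, 11 and 17 lines, and batch 3 held too few lines. For Fanconi and homologous recombination genes it was 0.534, -0.617, 0.339 and 0.611, for NF-kB target genes 0.578, 0.137, 0.248 and 0.765, for interferon-stimulated genes 0.806, 0.514, 0.163 and 0.407, and for ribosomal protein genes 0.264, -0.856, -0.216 and -0.604. With batch means removed, r was 0.433, 0.41, 0.417, 0.414 and -0.39 for these lists. Of genes, 1 of 18370 passed and 1606 had an unadjusted p under 0.05; the count was 0 without OVCAR-8 or M41, 3 without RMG-II or UWB1.289, 2 without HeyC2, OVCA429, C13, IGROV-1, Hey, DOV13A, OVCAR-5, PEO1 or TAYA, 6 in the single-pair lines and 4 in the replicated lines, where RNLS was not among them. For lists the count was 5 with batch means removed (adjusted p from 0.0288 to 0.0357) and 0 with 1 value per family of related lines, where r was 0.387, 0.362, 0.425, 0.411 and -0.357 (n = 40).

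**Figure D4:**
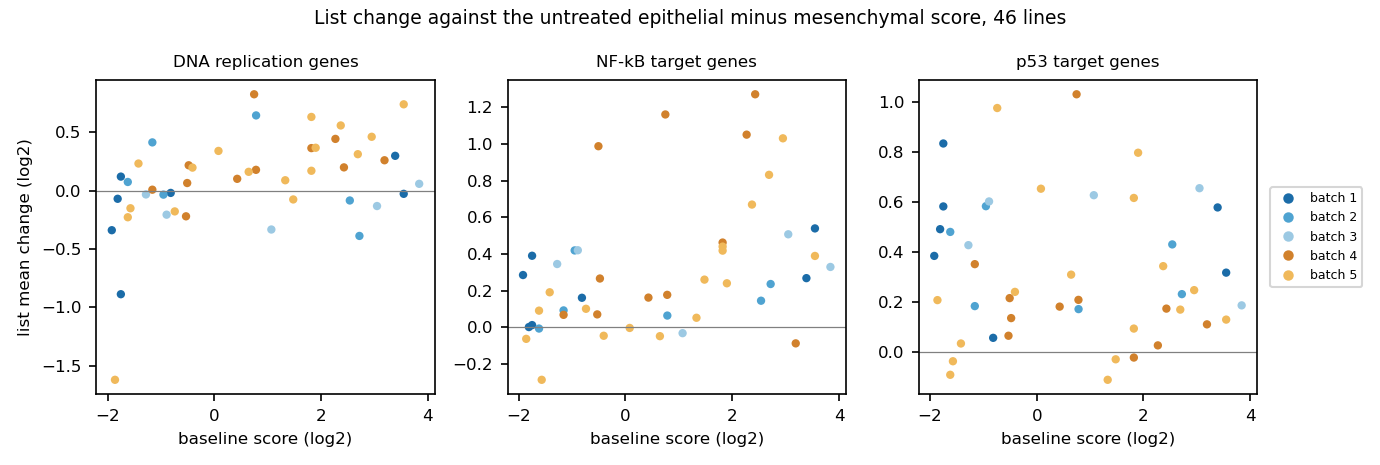
Mean log2 change of 3 gene lists in each of 46 lines (vertical) against the untreated epithelial minus mesenchymal score (horizontal, log2), coloured by batch. Pearson's r was 0.429 for DNA replication genes, 0.414 for NF-kB target genes and -0.0997 for p53 target genes.

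Since adducts on DNA obstruct RNA polymerase, gene length was examined. Over all 18389 genes with a length, the mean Spearman rho across genes between length and change was -0.0201 ± 0.0243 (SE, n = 46 lines, sign-flip permutation p = 0.415), negative in 23 lines; genes are not independent replicates. Among genes brighter than the median gene, those of 200 to 500 kb had a median change of -0.125 ± 0.0443 against the median gene (479 genes, lower in 33 lines, permutation adjusted p = 0.0064), and those over 500 kb -0.275 ± 0.0647 (66 genes, lower in 35 lines, adjusted p = 0.00012). Genes of 10 to 50 kb were at 0.0184 ± 0.00536 (4029 genes, adjusted p = 0.00159). The expressed genes longer than 200 kb were at -0.0222 ± 0.04 in 17 lines of batches 1 to 3 (permutation p = 0.729) and at -0.214 ± 0.0674 in 28 lines of batches 4 and 5 (permutation p = 0.00069), a difference with permutation p = 0.0405. FU-OV-1, of batch 2, was at -0.544 for 200 to 500 kb and -1.18 over 500 kb. In OVCA433, measured in both sets, the genes longer than 200 kb were at -0.000107 in batch 2 and -0.0762 in batch 4. The division by length and by set was chosen after seeing the data.

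**Figure D5:**
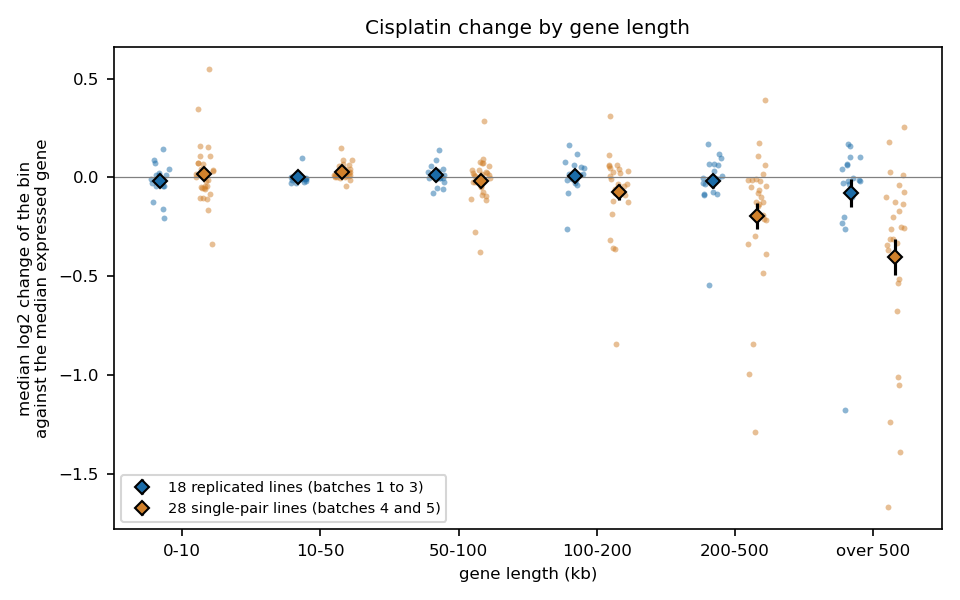
Median log2 change of expressed genes by gene length (kb) against the median expressed gene; points are lines and diamonds are means ± SE of 18 replicated and 28 single-pair lines. Lines of batches 4 and 5 lay lower for genes over 500 kb.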

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

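The tests of array sets, of the long genes in single sets, of adduct-blocked elongation, of S phase and of dim genes on unlike scales, and the exchanges of cultures between related lines, were chosen or had conditions added only after the result was seen, as were the lines named for long genes. The other tests were fixed before.

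The effect of cisplatin differed between the 18 replicated lines for 9401 genes, by an F test of the difference between lines. Random relabelling of the cultures within every line gave as many in 1 of 100 draws, the real one included, and the highest other count was 2639. The median count within lines was 857, again as large in 1 of 100 draws with a highest other median of 4. Over all lines the 1787 genes were matched in 1 of 100 draws with arms swapped in random lines, with a highest other count of 53, so chance can be excluded for these 3 results. In single lines 10 splits are too few for a share under 0.05: the real split was alone in calling the most genes in 15 of 17 lines, which is 1 of 10 splits. In TYK-nu the real split gave 14 genes against 203 for another and in A2008 949 against 1055, which is 2 of 10 splits each, and in PA-1 another split reached 2182.

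The response of C13 differed from that of A2008 for 888 genes, of HeyC2 from HeyA8 for 139 and of DOV13B from DOV13 for 15, each by a test of the difference. Relabelling arms at random within both lines gave as many genes in 4, 32 and 9 of 100 draws, with highest other counts of 2080, 1925 and 727. Draws that call several times the real count point to a structure of the samples, since a draw that turns the arms of 1 line adds the effects of both lines. The shares are therefore too high, so chance can be excluded for C13 and A2008 and the shares decide nothing for the other pairs. Exchanging cultures between the lines within an arm gave as many in 1 of 100 draws for each pair, with highest other counts of 554, 131 and 2. The margin for HeyC2 and HeyA8 was small, at 139 against 131. In this later test each culture was first centred on its line's mean of both arms. Such centring ties the arms together in the real labelling but not in the draws, which can favour the real count. Chance is therefore not excluded for HeyC2 and HeyA8 or for DOV13B and DOV13. The count of 15 for DOV13B and DOV13 was 1 without the untreated culture 1 of DOV13. For the slope on the baseline score, the 1 gene was matched or exceeded in 3 of 100 permutations, the highest with 3 genes. A single call comes in up to about 5% of such draws by the adjustment alone, so chance is not excluded for it, and 0 genes passed without OVCAR-8 or M41.

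Expressed genes longer than 200 kb lay 0.139 below the median gene, at -0.139 ± 0.0454 (SE, n = 46, lower in 34 lines, permutation p = 0.00115). Long genes in the upper quartile of brightness, averaged over all arrays, were at -0.118 (permutation p = 0.00755, lower in 27 of 46 lines). This argues against dim signal near background for all lines together. Brightness within batches 4 and 5, where the fall was larger, was not tested, so dim signal there stays open. Array scale or quality of batches 4 and 5 may contribute over the lines, because the replicated lines of batches 1 to 3 were at -0.0223 (permutation p = 0.706), and set and lines cannot be told apart. Those batches do not hold FU-OV-1, in which all 9 pairings of a treated with an untreated culture were below 0 with the highest at -0.466. All were below 0 too in OV90 and OVCAR-8 (highest -0.056 and -0.048). In FU-OV-1 348 of 545 long genes fell, or 63.9% against 15.2% of all expressed genes, and 7 rose. By contrast, in PA-1 125 rose and 21 fell (pairings from 0.0626 to 0.254) and in C13 121 and 30 (0.0545 to 0.197). In A2008 25 rose and 8 fell (0.0147 to 0.196), in DOV13 30 and 1 (0.0137 to 0.0925) and in OVCAR-10 50 and 3 (-0.0327 to 0.244). Elongation blocked by adducts stays open as a hypothesis, with a mean rho of -0.0371 between length and change over 2645 expressed genes of 50 to 200 kb (permutation p = 0.0352, 28 of 46 lines negative).

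Replication-dependent histone genes fell by 0.35 on average. Poorer capture of RNA without a poly(A) tail was not seen in small nucleolar RNA genes, which also lack one and were at 0.0387 ± 0.0338 (SE, n = 46, 192 genes). Whether their signal lay above background, and whether they are captured as histone RNA is, was not tested, so this explanation stays open. Fewer cells in S phase may contribute and stays open: the histone and DNA replication means correlated over 46 lines with r = 0.35 (permutation p = 0.0185, adjusted p = 0.037 over 2 relations; rho = 0.265, p = 0.0772), and with r = 0.35 without the 2 farthest lines. Within batches 1, 2, 4 and 5 r was 0.716, 0.73, 0.72 and -0.0737, and with batch means removed it was 0.245 (permutation p = 0.101), which keeps it open. The DNA replication list itself did not fall over the 46 lines, with a mean of 0.08 ± 0.06, positive in 28 lines. Its means in batches 1 to 5 were -0.13, 0.10, -0.13, 0.22 and 0.12. No measure of the cell cycle other than expression was analysed here.

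The response differed between lines of batches 1 to 3 and lines of batches 4 and 5 for 14 genes by limma, 4 with a higher and 10 with a lower change in batches 4 and 5, and 1711 had an unadjusted p under 0.05. Random splits of the lines gave as many in 1 of 100 draws and a highest other count of 0, so chance can be excluded. Hybridisation or processing of the batches could not be settled: in OVCA433, the 1 line measured in both sets, batch 4 minus batch 2 had the sign of the set difference for 92.9% of these genes, with a median of 0.341 of its size. Dim genes on unlike scales could not be settled, with 0.13% of the genes in the upper quartile of brightness different against 0.076% of all (Fisher's exact p = 0.129). The lines themselves differ between the sets, so a difference of biology stays open and untested.

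The genes of that comparison, named after their values were seen, included the p53 target PHLDA3, at 0.38 in batches 1 to 3 and -0.05 in batches 4 and 5, CD82 at 0.53 and -0.14, and CEBPG at -0.13 and 0.39. H4C14 and H4C15, near-identical copies with the same values that count as 2 genes, were at -0.85 and 0.18. In OVCA433 the changes in batches 2 and 4 were 0.34 and 0.325 for PHLDA3, 0.138 and 0.0666 for CD82, 0.189 and 0.19 for CEBPG and -0.721 and -0.149 for H4C14, so PHLDA3 and CEBPG hardly differed between the sets in that line.

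Among 13837 probe sets outside the named genes, 125 passed the threshold over all lines, 63 higher and 62 lower, and 1290 had an unadjusted p under 0.05. This was a signal in data that the comparisons did not use: 61 of the 125 carried several symbols and 64 were not listed in the annotation. The share past the threshold was 0.903%, against 9.70% of the named genes.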

How the results depend on the processing

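Alternatives that left out Hey, doubtful lines, the lines of a batch or OVCAR-10, counted CH1 with PA-1, standardised the score within batch or counted families once for lists against the score were chosen after seeing the data; the others were planned. Of 3786 values of named genes under these alternatives, 2800 kept their direction and side of the threshold, 940 were no longer past it, 29 were newly past it and 17 reversed, and for list means the numbers were 389 of 486, 80, 13 and 4. The cause of a change was not tested except where fewer lines or cultures entered. Low signal over background limits dim genes.

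Over all lines the count of 1787 became 2 with no replicate block, that is without pairing by line, 4246 with arrays as replicates, 638 with batches weighted equally, 987 in the single-pair lines, 6 with a minimum change of 1.2-fold and 627 without the lines of batch 4. In batches 1 to 5 alone it was 2, 2, 6, 770 and 16. Leaving out each line gave 1570 to 2373, the highest without Hey, and without Hey, OAW28, SKOV-6 and OVCAR-10 it was 2336. The replicated lines gave 1335 genes, 552 of them among the 1787. With 1 difference per family of related lines 2115 genes passed, and 2133 with CH1 counted with PA-1 too. The share of higher genes was 51.3%, and 59.9% with arrays centred on their median. Among genes past the threshold in both the main fit and the alternative, 0 changed sign. The fits share lines, so a change of sign among such genes was hardly possible.

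Reversed were, in batch 1 alone, CPQ at 0.057, RFC3 at -0.11, E2F2 at -0.031, EXO1 at -0.12, XRCC2 at -0.13, POLQ at -0.051, PDIA4 at 0.036 and CLDN3 at 0.12, in batch 2 alone PPIA at 0.049, and in batch 3 alone POLA2 at -0.038, E2F2 at -0.00314, EXO1 at -0.011, ME1 at 0.026 and KRT19 at 0.30. MDM2 was at -0.12 in batch 4 alone, and KRT19 at 0.030 and CLDN3 at 0.020 in the replicated lines. The housekeeping mean was 0.00157, 0.0176 and 0.021 in batches 1, 2 and 3 alone, and the platinum transport mean 0.0569 in batch 3 alone.

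The count of 14 lists became 6 with an estimated correlation, 9, 0, 0, 4 and 7 in batches 1 to 5 alone and 9 without batch 4; with 5 lines in batch 3 and 6 in batch 2 the smallest p possible was 0.0625 and 0.0312, so no list could pass in batch 3 and few lines limited batch 2. The 5 list correlations with the score stayed 5 with batch means removed and became 0 without the 2 farthest lines, 0 with 1 value per family and 0 without Hey, OAW28, SKOV-6 and OVCAR-10. The 1 gene with a slope became 2 with batch as a term, 4 in the replicated and 6 in the single-pair lines, 2 with 1 value per family, 0 with the epithelial genes alone and 2 with the mesenchymal genes alone, 0 among genes above the median, 0 with arrays centred on their median, 2 without Hey, 0 without Hey, OAW28, SKOV-6 and OVCAR-10 and 2 with the score standardised within batch; leaving out each line gave 0 to 3. The 0 among genes above the median leaves open whether RNLS was too dim to enter or failed the threshold. The length correlation of -0.0201 stayed short of the threshold, between -0.0341 and -0.0198.

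The numbers of the cultures did not pair them: over 53 same-numbered pairs the mean correlation of deviations was -0.0354, between -0.502 and 0.424, with 7 pairs over 0.1 and 0 of 18 lines with every pair over it. With the replicate block the median within lines was 652.5, the F test gave 8073 genes, and the contrasts gave 677 for C13 and A2008, 48 for HeyC2 and HeyA8 and 4 for DOV13B and DOV13.

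Without the cultures of 1 number, with a lone culture assumed to vary like the others, the median of 857 was 541.5, 188.5 and 595.5, and leaving out single cultures raised it to at most 1013, without the treated culture 1 of OVCAR-10. The F test ranged from 3694 to 8379. With each line fitted alone the median was 410, with a minimum change of 1.2-fold 81 and without OVCAR-10 1117. Leaving out cultures gave 91 to 1426 for C13 and A2008, 25 to 209 for HeyC2 and HeyA8 and 0 to 31 for DOV13B and DOV13. With only the lines of the contrast in the fit the counts were 72, 74 and 8. For HeyC2 and HeyA8 the count was 81 with arrays centred on their median and 233 among genes above the median, and for DOV13B and DOV13 it was 27 among genes above the median.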

Other observations

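The test of p53 targets against mitotic genes was fixed before its result was seen; the genes and lines named here were chosen after their values were seen.

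Among the replicated lines, some genes passed in most lines by the contrast of each line, with the spread pooled over lines. DDB2, a damage recognition factor, rose in 15 of 18 lines, the translesion polymerase gene POLH in 14, the phosphatase gene PPM1D in 14 with a fall in 1, and SAT1 in 14. MR1, which presents metabolites to T cells, rose in 13 lines and the adhesion gene CEACAM1 and SESN1 each in 12. HLA-DMA, the interferon-stimulated gene IFI6 and the cytidine deaminase gene APOBEC3C each rose in 11 lines. The histone gene H4C2 fell in 15 lines and rose in 1, and the histone chaperone gene SSRP1 and the helicase gene MCM6 fell in 11, MCM6 with a rise in 1.

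The size of group responses varied over the 46 lines. The p53 target mean ran from -0.11 in SKOV-8 to 1.03 in OAW42, with 0.98 in DOV13A and 0.83 in HeyA8. The NF-kB target mean was highest in PEO1 at 1.27 and lowest in OV56 at -0.29. The DNA replication mean was -1.62 in Hey and 0.82 in OAW42, and the mitotic mean -1.60 in Hey and 0.75 in SKOV-6; the treated array of Hey also had the lowest correlation with its batch, 0.801. The median change of genes over 500 kb was lowest in OAW28 at -1.67, UWB1.289 at -1.39 and OV56 at -1.24. The OAW28 arrays and the treated array of SKOV-6 were nearest to an array of another line, so their values are doubtful too.

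The hypothesis that p53 target induction goes with lower mitotic gene expression was tested over the 46 lines. The list means correlated with r = 0.116 (permutation p = 0.445, adjusted p = 0.445 over 2 relations; rho = 0.161, p = 0.282) and with r = 0.188 without the 2 farthest lines. Within batches 1, 2, 4 and 5 r was -0.608, 0.454, 0.238 and 0.175. The correlation did not differ from 0, which leaves the question open.

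By untreated profiles some lines with different names were alike: CH1 and PA-1 correlated at 0.874, SKOV-4 and SKOV-6 at 0.816 and M41 and OAW28 at 0.743, against 0.751 for HeyA8 and HeyC2 and a median of -0.0305 over 1035 pairs of lines. The untreated cultures of PA-1 and SKOV-3 in batch 5 belonged to no comparison; SKOV-3 untreated in batches 4 and 5 differed by a median absolute log2 value of 0.199.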
